A study of Mus musculus with 24 samples.

How the data were processed

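Gene expression was measured by RNA sequencing in granulosa cells and oocytes of mouse follicles cultured in alginate, in 6 groups of 4 libraries (2 cell types under control, blebbistatin at 20 µM or dextran at 10 kPa). Per the labels' protocols, the follicles grew with 50 mIU/ml FSH to day 3, those past 180 µm were separated mechanically, RNA of all replicates was extracted together, and cDNA was amplified over 15 PCR cycles. Each oocyte library pooled 1 to 2 oocytes. The labels call the replicates biological but do not say whether they came from separate animals or cultures, nor whether the control medium held the solvent of blebbistatin. The deposited values are estimated counts per gene from salmon, per the labels, in 2 tables of 78298 genes, 1 per cell type. The genome build was GRCm39, per the submitters' processing notes. The aligner, the annotation release, the software versions and the strandedness of the counting are not given in the sources used here. The authors' totals differ between libraries, and 0 sample columns were left unused. Genes are named by the symbols and Ensembl identifiers of the deposited tables, and no coordinates are given because the reference at hand is of another build.

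Estimated counts were rounded to whole numbers. Genes were filtered with filterByExpr, libraries scaled with TMM factors, and each cell type fitted apart over its 12 libraries with edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest) in R 4.3.3. The p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05, which left 15370 genes tested in granulosa cells and 16749 in oocytes. The difference between cell types was tested as an interaction over all 24 libraries and 20601 genes, with each gene's spread shared by both cell types. CPM in the text are TMM-scaled, with exceptions that are relative to the unscaled library total. These are the plot of 8 genes, the single-library values of Lyz2 and Inha, the levels of Ftl1-ps1, the marker levels and the level of granulosa genes in oocyte libraries. Reads without molecular identifiers are not independent molecules, so the depth of 14244100 to 22431000 counts per library limits counting error only.

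Before the data were examined, 34 gene lists were fixed from textbook knowledge, with 830 entries and 783 distinct genes, of which 7 lists are markers of cell types. Akr1b3 was the 1 listed gene absent from the tables. A list was tested where at least 5 members passed the filter, with camera of limma 3.58.1 and a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Alternatives were a correlation estimated per list and fry, which tests whether a list's genes move on balance in 1 direction and does not compare them with other genes. Members are also counted past the threshold adjusted over the list alone. The counts of lists include 1 list that is not reported here, which was called rising for each treatment in granulosa cells, kept that call without any 1 library and was 1 of the 2 that passed for dextran with an estimated correlation. Marker levels are means of log2(CPM + 1) over a list. They and the library measures were compared by exact two-sided permutation tests of 4 against 4 libraries, 48 tests in all, whose smallest possible p is 0.0286.

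Genes named in the text follow a rule fixed at the same time. It takes the 6 genes per direction with the smallest adjusted p among those that passed, with a symbol and a mean of at least 5 CPM. Where fewer than 3 passed it takes the 3 of smallest unadjusted p, said not to have passed. It adds up to 2 rising and 2 falling members of each list described, and anchor genes of myosin II, YAP signalling, granulosa function, oocyte factors and osmotic response. For blebbistatin against dextran and the difference between cell types it takes 3 genes per direction and those already named.

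The steps were tested on simulated data with 200 changed genes, 100 of each fold, drawn from genes with a mean of at least 5 CPM. Genes were simulated independently of each other and around the mean of all libraries. The simulated libraries therefore lacked the differences in make-up between real ones. For dextran against control in granulosa cells (14821 genes) edgeR found 40% of 2-fold and 69% of 4-fold changes with 3 false calls among 112. Limma voom made 2 false calls among 99 and DESeq2 51 among 191. For dextran in oocytes (16214 genes) edgeR found 67% and 94% with 9 false calls among 170, limma voom made 5 among 163 and DESeq2 39 among 213. With no change simulated edgeR and limma voom called 0 genes, and a list raised by 0.5 on the log2 scale was found. With the 200 genes changed and no list raised, camera still called 2 lists in granulosa cells and 1 in oocytes. Replicates of each group were compared with a chi-square test per gene with at least 10 counts. The smallest value was 12.4 per gene, far above sampling noise, so no library was counted as a duplicate.

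The alternatives were size factors of DESeq2 (RLE), no count filter (any gene with at least 1 count), a stricter filter (5 CPM in at least 4 libraries), limma voom with quality weights, DESeq2 1.42.0, a fit of only the 2 groups compared, the replicate number as a block, and each library left out in turn. Alternatives chosen after seeing the data left out 2 control oocyte libraries with many granulosa cell transcripts, 2 blebbistatin granulosa libraries with macrophage transcripts, or blebbistatin granulosa replicate 1, the granulosa library with the fewest genes detected. Each test between groups was repeated over the 35 mirrored splits of its 8 libraries, and the interaction over 40 regroupings. Libraries standing apart from their group were sought with Dixon's ratio among library measures and the genes named by p or as anchors. Plots were drawn with matplotlib 3.10.9 from tables written with pandas 2.3.3 in Python 3.11.15.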

Results

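RNA sequencing measured gene expression in granulosa cells and oocytes of wild-type mouse ovarian follicles that had been enclosed in alginate, a polysaccharide gel, and cultured to day 3 with FSH at 50 mIU/ml. Granulosa cells are the somatic cells that surround and nourish the oocyte. The follicles grew in control medium, in medium with 20 µM blebbistatin, which blocks the motor protein myosin II, or in medium with dextran at 10 kPa, a polysaccharide that compresses the follicle by osmotic pressure. Follicles that had grown past 180 µm were taken apart mechanically into oocytes, pooled 1 to 2 per library, and granulosa cells, pooled in larger numbers. Each of the 6 groups had 4 libraries, 24 in all. Total counts ran from 16432300 to 22431000 per granulosa cell library and from 14244100 to 18399600 per oocyte library. The labels call the replicates biological but do not say whether they came from separate animals or cultures. The p-values therefore measure the spread between these libraries, part of which may be technical. Levels are given as CPM (counts relative to the scaled library total), mean ± SD of 4 libraries, and log2 changes with their standard errors (SE).

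The blebbistatin comparison in granulosa cells asks which transcripts moved when myosin II was blocked. Ftl1 (ENSMUSG00000050708), the light chain of the iron-storage protein ferritin, rose from 1846 ± 248 to 3759 ± 472 CPM (n = 4 per group). That was a log2 change of 1.03 ± 0.12, with all 4 blebbistatin libraries above all 4 controls. It was the 1 gene of 15370 tested to pass (edgeR quasi-likelihood test, adjusted p = 0.0214). Genes of the actin cytoskeleton and of its transcriptional regulator SRF rose as a group. Of the 30 tested members 27 had a positive log2 change, the median was 0.54, and 12 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 3.37e-13; adjusted p = 0.0547 with an estimated correlation). Tpm1, a tropomyosin that stabilises actin filaments, was at 615 ± 177 against 177 ± 65.5 CPM, and Fhl2, a LIM-domain cofactor of SRF, at 51.6 ± 23.1 against 10.4 ± 5.51 CPM. The lower member was Fhl1, a LIM-domain protein of muscle, with a log2 change of −2.98 ± 1.04. The myosin II heavy chains showed log2 changes of −0.24 ± 0.23 (Myh9) and 0.14 ± 0.13 (Myh10), and the light chain Myl9 one of 2.34 ± 0.83 (edgeR adjusted p = 0.346).

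Extracellular matrix genes rose in the same libraries, and so did markers of other cell types. Of 20 interstitial matrix genes, 5 were higher and 1 lower adjusted over the list alone (median 1.54, camera adjusted p = 3.93e-06; adjusted p = 0.174 with an estimated correlation). Thbs2, a matricellular thrombospondin, was at 31.4 ± 18.98 against 1.43 ± 1.26 CPM, while its relative Thbs1 was at 340 ± 97.1 against 724 ± 313 CPM. Of 21 basement membrane genes, 8 were higher and 2 lower adjusted over the list alone (camera adjusted p = 0.000449; adjusted p = 0.174 with an estimated correlation; 0.0642 without blebbistatin replicate 3). They included the collagen IV chain Col4a4, at 61.1 ± 52.7 against 5.46 ± 2.93 CPM, and Sparc, a collagen-binding protein, at 574 ± 364 against 108 ± 53.6 CPM. The glycoprotein Fbln1 was lower, at 144 ± 52.7 against 259 ± 18.1 CPM. Matrix remodelling genes rose (median 0.68, 4 of 22 higher adjusted over the list alone, limma camera adjusted p = 0.00219), among them the collagen cross-linking enzyme Lox (log2 change 3.32 ± 0.98). Focal adhesion genes rose too (median 0.20, 3 of 26 higher adjusted over the list alone, limma camera adjusted p = 0.000449), among them the fibronectin receptor Itga5 (1.32 ± 0.31). Both lists had an adjusted p = 0.174 with an estimated correlation. Stromal and smooth muscle markers rose with them. Of 15 markers 7 were higher adjusted over the list alone (median 2.26, camera adjusted p = 9.83e-10; adjusted p = 0.174 with an estimated correlation). The chemokine gene Cxcl12 was at 37.0 ± 36.2 against 2.35 ± 1.62 CPM. The mean stromal marker level on the log2(CPM + 1) scale was 4.33 ± 0.66 against 2.49 ± 1.07. Its exact two-sided permutation p of 0.0286 is the smallest that 4 against 4 libraries can give, and the adjusted p was 0.549 over 48 such permutation tests. The YAP and TAZ target list, read as a response to mechanical load, rose (median 0.45, camera adjusted p = 0.00176; adjusted p = 0.184 with an estimated correlation) with 0 of 23 members past the threshold adjusted over the list alone by edgeR. Log2 changes of 3 of its best-known members were 1.06 ± 0.75 (Ccn1), 1.94 ± 1.04 (Ccn2) and 1.48 ± 2.07 (Ankrd1).

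Granulosa cell genes moved the other way. The FSH response and steroidogenesis list fell, with 8 of 28 members lower and 1 higher adjusted over the list alone (median −0.42, camera adjusted p = 3.86e-05; adjusted p = 0.174 with an estimated correlation). The granulosa cell markers fell, with 7 of 20 lower adjusted over the list alone (median −0.34, camera adjusted p = 0.000152; adjusted p = 0.174 with an estimated correlation). Inhbb, the beta B subunit of inhibin and activin, was at 99.2 ± 21.6 against 522 ± 292 CPM, and Inha, the inhibin alpha subunit, at 11761 ± 1300 against 16599 ± 1119 CPM, both with all 4 blebbistatin libraries below the controls. The higher member was Sphk1, a sphingosine kinase, with a log2 change of 2.35 ± 0.62. The log2 change was −1.40 ± 0.49 for the FSH receptor gene Fshr, −1.40 ± 0.79 for the anti-Müllerian hormone gene Amh and −3.39 ± 2.17 for aromatase (Cyp19a1). It was −0.33 ± 0.11 for the gap junction gene Gja1, 0.47 ± 0.36 for Kitl, the ligand of the oocyte's Kit receptor, and −0.40 ± 0.30 for Slc5a3. None of these 6 passed over all genes. The granulosa marker level per library was 7.59 ± 0.18 against 8.23 ± 0.36 (exact two-sided permutation p = 0.0571, adjusted p = 0.549).

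Further groups moved with them. The AhR and NRF2 response list, genes induced by xenobiotics and oxidants, rose with 7 of 23 members higher adjusted over the list alone (median 0.36, camera adjusted p = 3.80e-09; adjusted p = 0.0547 with an estimated correlation). It holds Ftl1 and also the haem oxygenase gene Hmox1, at 91.6 ± 20.3 against 38.3 ± 6.02 CPM. All 12 tested mitochondrially encoded genes were higher adjusted over the list alone (median 0.95, camera adjusted p = 1.31e-18; adjusted p = 0.138 with an estimated correlation). Their share of counts was 5.77 ± 2.04% against 3.05 ± 0.80% (exact two-sided permutation p = 0.0571). Genes detected per library numbered 18410 ± 2791 against 22656 ± 1478 (exact two-sided permutation p = 0.0571), with 14501 in blebbistatin replicate 1. Immune cell markers rose (2 of 5 higher adjusted over the list alone, camera adjusted p = 0.0373; adjusted p = 0.356 with an estimated correlation). The call ended without blebbistatin replicate 1 (0.0577) or 2 (0.611). The macrophage gene Lyz2 stood at 374 and 647 CPM in blebbistatin replicates 1 and 2 and at 0 in replicates 3 and 4. Hypoxia and glycolysis genes fell (median −0.60, 0 of 27 past the threshold adjusted over the list alone by edgeR, camera adjusted p = 0.00247; adjusted p = 0.548 with an estimated correlation; 0.0747 without control replicate 3). Heat shock genes rose (2 of 20 higher adjusted over the list alone, camera adjusted p = 0.00776; adjusted p = 0.174 with an estimated correlation; 0.0502 without control replicate 4). Cryab, a small heat shock protein, was at 41.2 ± 16.8 against 11.2 ± 8.01 CPM. The TGF-beta, BMP and activin response list rose (2 of 22 higher adjusted over the list alone, camera adjusted p = 0.0381; adjusted p = 0.487 with an estimated correlation). It lost its call without blebbistatin replicate 1 (0.0680) or 4 (0.264) or control replicate 1 (0.292) or 2 (0.105). Its 2 higher members were the BMP targets Id1 and Id2.

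Beside Ftl1, 1602 genes had an unadjusted p under 0.05 (824 higher, 778 lower). The 4 blebbistatin libraries did not overlap the 4 controls for 1014 genes, 6.60% of those tested, where chance gives 2.86%. The next genes by p did not pass. They were Rpl22l1, a ribosomal protein paralog (log2 change 0.69 ± 0.12, edgeR adjusted p = 0.0968), and Col4a4 (3.49 ± 0.61, 0.102) on the higher side. On the lower side they were the phospholipase-like Plbd1 (−1.49 ± 0.21, 0.0606), the AMP kinase subunit Prkag2 (−0.90 ± 0.13, 0.0606) and the peroxiredoxin Prdx4 (−0.64 ± 0.10, 0.0770). The count was 28 with limma voom and 415 with DESeq2. It was 4, 115 and 2 without blebbistatin replicate 1, 2 or 4, 4 without dextran replicate 3, and 26 without blebbistatin replicates 1 and 2 together, a setting chosen after seeing the data. It was 0 by edgeR without blebbistatin replicate 3, control replicate 1, 2 or 3 or dextran replicate 2 or 4, where Ftl1 had an adjusted p of 0.0665, 0.132, 0.0825, 0.0605, 0.0548 and 0.0526. It was also 0 by edgeR with the replicate number as a block, where Ftl1 had an adjusted p of 0.0903, and with only the 2 groups compared (0.179). Over 21 alternatives the adjusted p of Ftl1 ran from 2.58e-09 to 0.179 and its log2 change from 0.89 to 1.13. Of 32 lists tested 16 passed (13 rising, 3 falling), and 17 without blebbistatin replicates 1 and 2. For 4 of the 16 the real grouping gave a smaller camera p than every other split of the libraries. With an estimated correlation camera called 0, with 8 lists at an unadjusted p under 0.05, and fry called 7, of which 5 were among the 16.

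**Figure D1:**
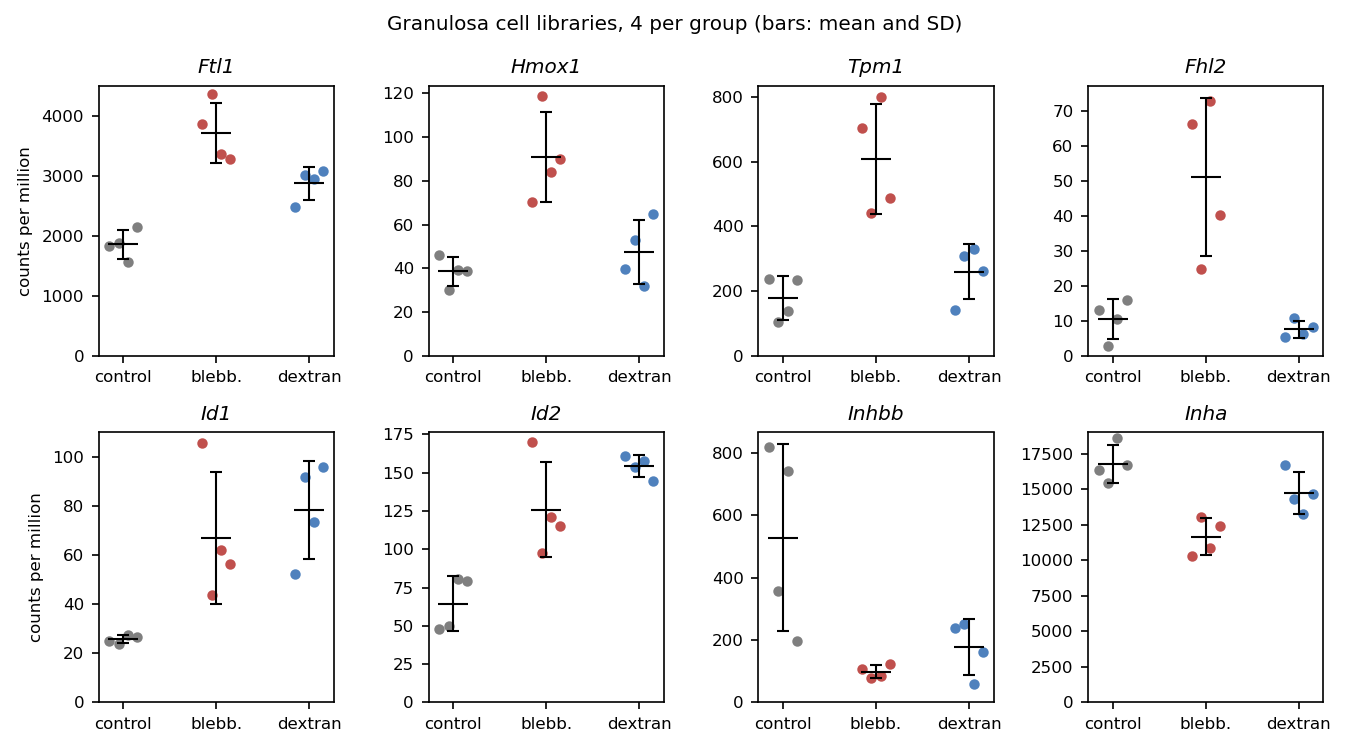
CPM, relative to the unscaled library total, of 8 genes in the granulosa cell libraries, 4 per group, with 1 point per library and bars for the mean and SD; each vertical axis starts at 0. Ftl1 lay between 3286 and 4369 CPM in the blebbistatin libraries and between 1565 and 2159 in the controls.

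The dextran comparison in granulosa cells asks what compressive stress changed. BMP and TGF-beta targets stood first. Id1 and Id2, inhibitors of differentiation that BMP signalling induces, were at 78.6 ± 19.1 against 25.5 ± 1.24 CPM and at 155 ± 8.66 against 63.7 ± 17.4 CPM (n = 4 per group). Their log2 changes were 1.63 ± 0.25 and 1.28 ± 0.20, each with all 4 dextran libraries above the controls. Neither passed over all genes (edgeR adjusted p = 0.174 for both), nor did Cd63, a tetraspanin of late endosomes, at 382 ± 56.8 against 245 ± 6.34 CPM (0.174). The TGF-beta, BMP and activin response list rose, with 19 of 22 log2 changes positive, a median of 0.50 and 4 members higher adjusted over the list alone (camera adjusted p = 7.31e-14; adjusted p = 0.0339 with an estimated correlation). This list was 1 of the 16 that passed.

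Immediate early genes rose (21 of 23 positive, median 0.92, 2 higher adjusted over the list alone, camera adjusted p = 1.24e-13; adjusted p = 0.0754 with an estimated correlation). Ier3, an early survival factor, was at 43.4 ± 16.3 against 13.5 ± 4.31 CPM and the AP-1 subunit Jun at 192 ± 61.5 against 75.4 ± 36.7 CPM. Focal adhesion genes rose (median 0.30, 22 of 26 positive, camera adjusted p = 2.17e-06; adjusted p = 0.0865 with an estimated correlation). YAP and TAZ targets rose (median 0.49, 19 of 23 positive, camera adjusted p = 4.03e-06; adjusted p = 0.106 with an estimated correlation), with 0 members of either list past the threshold adjusted over the list alone by edgeR. Gadd45b, a stress-induced YAP target, was at 88.2 ± 54.1 against 31.3 ± 16.3 CPM. The log2 changes of Ccn1, Ccn2 and Ankrd1 were 1.48 ± 0.76, 1.44 ± 1.02 and −2.39 ± 2.23. The AhR and NRF2 list rose (median 0.19, camera adjusted p = 0.00026; adjusted p = 0.106 with an estimated correlation) with 1 of 23 members higher adjusted over the list alone, Ftl1 at 2898 ± 234 CPM. The SRF and actin list was called rising (camera adjusted p = 6.79e-05; adjusted p = 0.224 with an estimated correlation; 0.0577 without control replicate 2). Its median log2 change was 0.24 and its mean −0.04. Its 1 of 30 members higher adjusted over the list alone was the cytoplasmic actin Actg1, at 784 ± 97.5 against 523 ± 94.5 CPM, while the smooth muscle gene Tagln had a log2 change of −1.42 ± 0.79. The stromal marker list fell (median −0.24, 0 of 15 past the threshold adjusted over the list alone by edgeR, camera adjusted p = 0.0277; adjusted p = 0.624 with an estimated correlation). That call was lost without blebbistatin replicate 1 (0.0968), control replicate 1 (0.334) or 4 (0.606) or dextran replicate 3 (0.483) or 4 (0.380). The stromal marker level was 2.08 ± 1.21 against 2.49 ± 1.07 (exact two-sided permutation p = 0.686). Matrix remodelling genes rose (1 of 22 higher adjusted over the list alone, camera adjusted p = 0.00317; adjusted p = 0.178 with an estimated correlation). Its call was lost without control replicate 2 (0.105) or 3 (0.0532) or dextran replicate 2 (0.177). Mmp11, a stromelysin, was at 393 ± 159 against 145 ± 36.9 CPM.

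Hypoxia and glycolysis genes fell (25 of 27 negative, median −0.36, camera adjusted p = 1.35e-06; adjusted p = 0.408 with an estimated correlation), with Gapdh, a glycolytic enzyme, at 798 ± 181 against 1139 ± 270 CPM. Cholesterol synthesis genes (22 of 24 negative, median −0.27, limma camera adjusted p = 0.000237) and unfolded protein response genes (21 of 26 negative, median −0.19, 0.000434) fell. So did granulosa markers (15 of 20 negative, median −0.16, limma camera adjusted p = 0.0081), the FSH response list (20 of 28 negative, median −0.22, 0.00884) and nuclear oxidative phosphorylation genes (27 of 34 negative, median −0.06, 0.046). Mitochondrially encoded genes rose (12 of 12 positive, median 0.23, limma camera adjusted p = 0.00308). None of these 7 lists had a member past the threshold adjusted over the list alone by edgeR. With an estimated correlation the last 6 had an adjusted p = 0.602, 0.438, 0.435, 0.491, 0.752 and 0.602 in the order given. Those 6 lists also lost their call when single libraries were left out. The libraries were control replicate 2 (0.152) or dextran replicate 3 (0.0831) for cholesterol synthesis and control replicate 2 (0.113) or dextran replicate 3 (0.0533) for the unfolded protein response. They were control replicate 3 (0.0532) for granulosa markers, and control replicates 1 (0.0689) and 3 (0.0918) or dextran replicate 3 (0.120) for the FSH list. Nuclear oxidative phosphorylation lost it without blebbistatin replicate 1 (0.0562), 3 (0.0574) or 4 (0.0558), control replicate 1 (0.0629) or 2 (0.516) or dextran replicate 3 (0.529). The mitochondrial genes lost it without control replicate 3 (0.240) or 4 (0.128) or dextran replicate 1 (0.166). The granulosa marker level was 7.90 ± 0.289 against 8.23 ± 0.356 and the mitochondrial share 3.50% against 3.05%. Inhbb was at 180 ± 90.0 against 522 ± 292 CPM, Inha at 14849 ± 1775 against 16599 ± 1119 and Amh at 132 ± 165 against 202 ± 129. Fshr was at 43.4 ± 21.4 against 67.9 ± 9.34 CPM and Kitl at 154 ± 71.7 against 98.7 ± 35.2, and none of these 5 passed. The osmotic stress list was not called (median 0.12, 0 of 15 members past the threshold adjusted over the list alone by edgeR, limma camera adjusted p = 0.287). The inositol transporter Slc5a3, a target of the osmotic regulator NFAT5, was at 30.8 ± 8.74 against 28.4 ± 6.36 CPM.

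By edgeR 0 of 15370 genes passed for dextran against control in granulosa cells, with 523 at an unadjusted p under 0.05 (365 higher, 158 lower) and a smallest adjusted p of 0.174. Limma voom called 143 (121 higher, 22 lower) and DESeq2 45, and edgeR called 4 without blebbistatin replicate 1. The libraries did not overlap for 724 genes, 4.71% against 2.86% by chance. The lower genes of smallest p were the septin Septin4 (log2 change −1.28 ± 0.28, edgeR adjusted p = 0.574), the unconventional myosin Myo6 (−0.62 ± 0.15, 0.693) and the hedgehog ligand Dhh (−0.97 ± 0.24, 0.802), and none of them passed. Of 32 lists 16 passed (9 rising, 7 falling), 2 of them with an estimated correlation, and fry called 1. The real grouping gave a smaller camera p than every other split of the libraries for 3 of the 16.

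**Figure D2:**
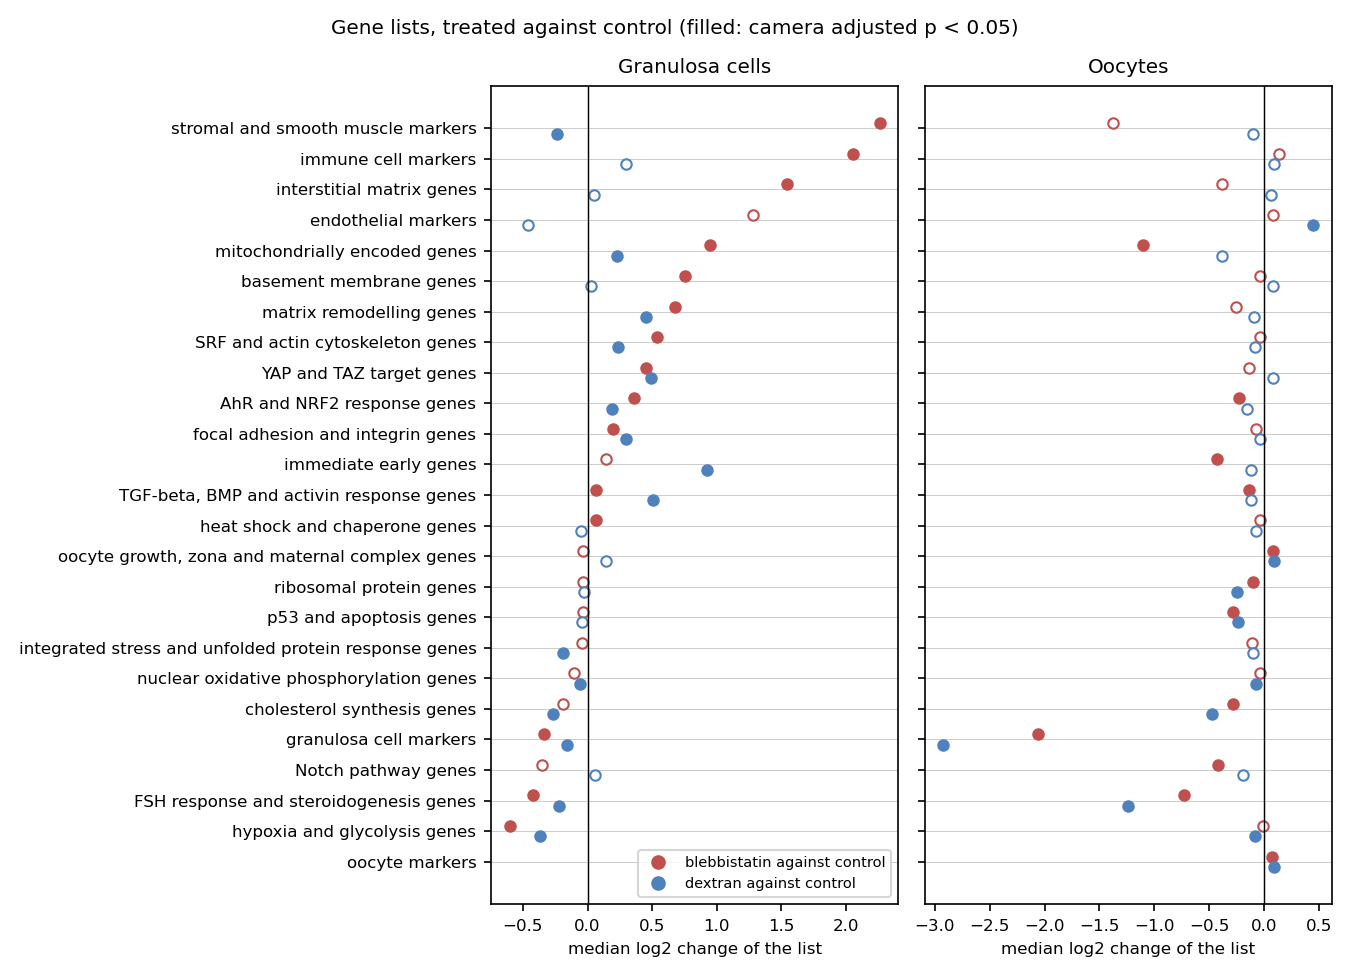
Median log2 change of gene lists against control, for blebbistatin (red) and dextran (blue), in granulosa cells (left) and oocytes (right); filled points passed limma's camera test with the preset correlation. Stromal markers in blebbistatin granulosa cells have a median of 2.26 and granulosa cell markers in dextran oocyte libraries one of −2.92.

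Between the granulosa cells of the 2 treatments camera called smooth muscle and immediate early genes, among others, but 0 lists passed with an estimated correlation. Stromal and smooth muscle markers were higher with blebbistatin than with dextran, 7 of 15 adjusted over the list alone (median 2.63, camera adjusted p = 2.71e-15; adjusted p = 0.247 with an estimated correlation). Among them the smooth muscle actin gene Acta2 was at 245 ± 172 against 26.7 ± 10.7 CPM and Tagln at 46.9 ± 28.0 against 3.66 ± 2.85 CPM. Interstitial matrix genes (4 of 20 higher and 1 lower adjusted over the list alone, limma camera adjusted p = 4.51e-07) and SRF and actin genes (8 of 30 higher and 1 lower, camera adjusted p = 1.11e-05) were higher with blebbistatin. So were AhR and NRF2 genes (1 of 23 higher, limma camera adjusted p = 0.000718), mitochondrially encoded genes (11 of 12 higher, camera adjusted p = 9.45e-13) and heat shock genes (1 of 20 higher, camera adjusted p = 0.00948). Each of these 5 lists had an adjusted p = 0.247 with an estimated correlation. Immediate early genes were lower with blebbistatin (5 of 23 lower adjusted over the list alone, median −0.55, camera adjusted p = 0.00136; adjusted p = 0.405 with an estimated correlation). This call was lost without blebbistatin replicate 2 (0.116) or 4 (0.0710). The early transcription factor Klf6 was at 34.5 ± 20.9 against 116 ± 5.87 CPM. TGF-beta response genes were lower with blebbistatin (median −0.36, camera adjusted p = 0.00595; adjusted p = 0.405 with an estimated correlation; 0.251 without blebbistatin replicate 2), with 0 of 22 past the threshold adjusted over the list alone by edgeR. The 4 other calls each ended without at least 1 library. Basement membrane genes (higher, camera adjusted p = 0.00971; adjusted p = 0.405 with an estimated correlation) lost theirs without blebbistatin replicate 1 (0.0761) or 3 (0.373). Immune markers (higher, camera adjusted p = 0.0361; adjusted p = 0.405 with an estimated correlation) lost theirs without blebbistatin replicate 1 (0.0637) or 2 (0.548). FSH response genes (lower, camera adjusted p = 0.0171; adjusted p = 0.422 with an estimated correlation) did so without blebbistatin replicate 2 (0.253) or dextran replicate 1 (0.227). Granulosa markers (lower, camera adjusted p = 0.0449; adjusted p = 0.430 with an estimated correlation) did so without blebbistatin replicate 1 (0.0803), 2 (0.253) or 3 (0.102) or dextran replicate 1 (0.407).

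Between these treatments 0 of 15370 genes passed by edgeR and 0 by limma voom, and 310 by DESeq2. By edgeR 1358 had an unadjusted p under 0.05 (608 higher and 750 lower with blebbistatin). The genes of smallest p, none of which passed, were Fhl2 (log2 change 2.75 ± 0.49, edgeR adjusted p = 0.240), the endosomal Rbsn (0.53 ± 0.10, 0.240) and Lbh (2.39 ± 0.46, 0.240) on the higher side. On the lower side they were the ubiquitin hydrolase Uchl1 (−1.40 ± 0.21, 0.231), the small GTPase Rhoa (−0.49 ± 0.08, 0.231) and Prdx4 (−0.56 ± 0.10, 0.231). The gene count was 3, 2 and 1 without blebbistatin replicates 1, 2 and 4. The libraries did not overlap for 864 genes, 5.62% against 2.86% by chance. Of 32 lists 12 passed (8 higher, 4 lower, and 7 in all without blebbistatin replicate 2). For 1 of the 12 the real grouping gave a smaller camera p than every other split. With an estimated correlation camera called 0, with 6 at an unadjusted p under 0.05, and fry called 2, of which 0 were among the 12.

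The blebbistatin comparison in oocytes asks the same of the germ cell. The lowest p belonged to Anp32b, a histone chaperone, at 139 ± 11.3 against 242 ± 34.4 CPM (log2 change −0.80 ± 0.12), and Ash2l, a core subunit of histone H3K4 methyltransferases, at 38.3 ± 2.82 against 70.8 ± 6.10 CPM (−0.89 ± 0.14). For both, all 4 blebbistatin libraries lay below the controls, and neither passed (edgeR adjusted p = 0.0865 for each). Noct, a circadian deadenylase-like gene, was at 76.6 ± 12.2 against 145 ± 19.9 CPM (0.527). Oocyte factors that drive follicle growth had log2 changes of 0.38 ± 0.19 (Gdf9) and 0.21 ± 0.17 (Bmp15). The zona pellucida gene Zp3 had one of 0.08 ± 0.17, the Kitl receptor Kit −0.08 ± 0.18, the gap junction gene Gja4 0.11 ± 0.13, Myh9 0.46 ± 0.32 and Slc5a3 −0.10 ± 0.57.

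Lists of granulosa cell genes fell in the blebbistatin oocyte libraries, granulosa markers among them (16 of 17 negative, median −2.06, camera adjusted p = 7.81e-05; adjusted p = 0.456 with an estimated correlation). The FSH response list fell too (19 of 21 negative, median −0.73, camera adjusted p = 2.96e-05; adjusted p = 0.451 with an estimated correlation). Amh was at 0.586 ± 0.469 against 14.7 ± 22.6 CPM. Over 10 granulosa genes the oocyte libraries held 8.80% of the granulosa pools' level in control replicate 2, 2.17% in control replicate 1, 2.04% in blebbistatin replicate 1 and at most 0.426% in the other 9. Inha stood at 1513 CPM in control replicate 2. In the same libraries cholesterol synthesis genes fell (21 of 23 negative, median −0.28, camera adjusted p = 2.46e-05; adjusted p = 0.399 with an estimated correlation). Ribosomal protein genes (60 of 77 negative, median −0.10, camera adjusted p = 7.81e-05; adjusted p = 0.501 with an estimated correlation) and mitochondrially encoded genes (11 of 12 negative, median −1.10, camera adjusted p = 0.00246; adjusted p = 0.467 with an estimated correlation) fell. The oocyte growth and zona list (22 of 27 positive, median 0.08, camera adjusted p = 0.00185) and the oocyte markers (21 of 24 positive, camera adjusted p = 0.00295) rose, both with an adjusted p = 0.451 with an estimated correlation. The p53, AhR and NRF2, immediate early, TGF-beta and Notch lists fell with camera adjusted p = 0.0108, 0.0143, 0.0164, 0.0198 and 0.0255 (adjusted p = 0.399, 0.399, 0.399, 0.451 and 0.399 with an estimated correlation). None of the 12 lists had another member past the threshold adjusted over the list alone by edgeR than these 2, both lower: the glutathione transferase Gsta4 (66.9 ± 9.10 against 121 ± 37.3 CPM) of the AhR and NRF2 list, and the BMP pseudoreceptor Bambi (3.74 ± 1.91 against 11.9 ± 4.37 CPM) of the TGF-beta list.

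By edgeR 0 of 16749 genes passed for blebbistatin against control in oocytes, with 686 at an unadjusted p under 0.05 (230 higher, 456 lower), 2 lower by limma voom and 19 by DESeq2. The higher genes of smallest p were Fahd2a (log2 change 0.96 ± 0.26), Necap2 (0.58 ± 0.17) and Bcas1 (0.49 ± 0.15), with edgeR adjusted p from 0.986. The libraries did not overlap for 437 genes, 2.61% against 2.86% by chance. Of 34 lists 12 passed (2 rising, 10 falling), 0 of them with an estimated correlation and 0 by fry, where 3 and 2 lists had an unadjusted p under 0.05. For 0 of the 12 did the real grouping give a smaller camera p than every other split. Without control replicate 2 camera called 0 lists, the 12 having adjusted p-values from 0.151 to 0.525, and it called 0 without control replicates 1 and 2, a setting chosen after seeing the data. Single calls also ended without blebbistatin replicate 2 (oocyte growth 0.126, oocyte markers 0.0972, TGF-beta 0.0943), 3 (TGF-beta 0.0629) or 4 (immediate early 0.227, Notch 0.0889, AhR and ribosomal both 0.107, mitochondrial 0.0517) or control replicate 3 (immediate early 0.168).

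**Figure D3:**
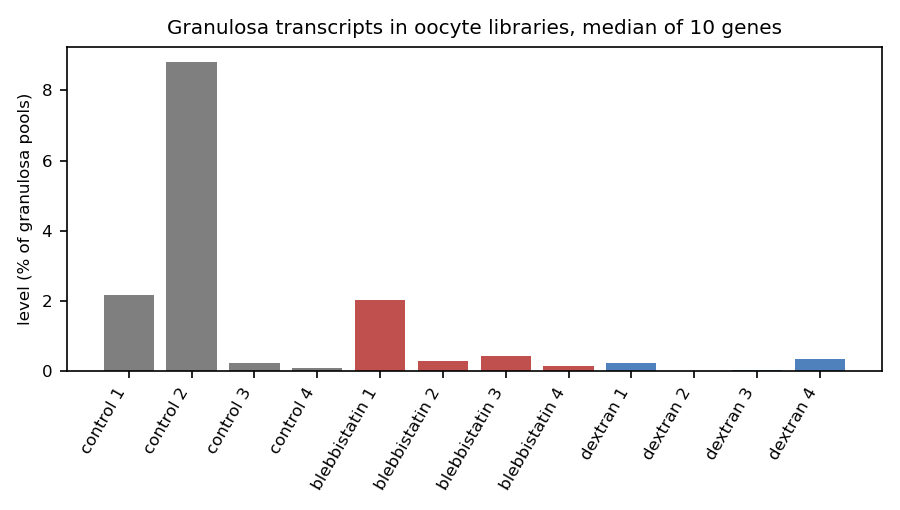
Level of 10 granulosa cell genes in each oocyte library, as the median percentage of their mean level in the granulosa cell pools; 1 bar per library, axis from 0. Control replicates 2 and 1 and blebbistatin replicate 1 stand at 8.80%, 2.17% and 2.04%.

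With dextran, ribosomal protein genes fell in the oocyte libraries. Of 77 log2 changes 75 were negative, with a median of −0.25 and 0 past the threshold adjusted over the list alone by edgeR (camera adjusted p = 2.14e-22; adjusted p = 0.368 with an estimated correlation). Rps3 was at 62.6 ± 3.05 against 105 ± 39.5 CPM. Ribosomal protein genes took 0.955 ± 0.0947% of counts against 1.14 ± 0.107% (exact two-sided permutation p = 0.0857). Cholesterol synthesis genes fell, with 7 of 23 lower adjusted over the list alone and a median of −0.48 (camera adjusted p = 6.67e-08; adjusted p = 0.368 with an estimated correlation). Fdps, which makes farnesyl pyrophosphate, was at 80.0 ± 2.42 against 145 ± 71.2 CPM, and Acat2, an acetyl-CoA acetyltransferase, at 15.6 ± 5.23 against 38.9 ± 25.6 CPM. Granulosa markers fell beside them (2 of 17 lower adjusted over the list alone, median −2.92, camera adjusted p = 2.34e-06; adjusted p = 0.396 with an estimated correlation), with Amh at 0.115 ± 0.231 against 14.7 ± 22.6 CPM. The FSH list fell as well (18 of 21 negative, median −1.24, camera adjusted p = 0.000455; adjusted p = 0.464 with an estimated correlation; 0.159 without control replicate 2). The dextran oocyte libraries held at most 0.327% of the granulosa pools' level of those genes, against the 8.80% and 2.17% of control replicates 2 and 1.

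Nuclear oxidative phosphorylation genes fell (25 of 34 negative, camera adjusted p = 0.00612; adjusted p = 0.368 with an estimated correlation), with the complex III subunit Uqcrfs1 at 48.9 ± 5.57 against 67.6 ± 6.81 CPM. The p53 and hypoxia lists fell (camera adjusted p = 0.0240 and 0.0333; adjusted p = 0.368 with an estimated correlation for both). Endothelial markers rose, with 1 of 7 higher adjusted over the list alone, the VEGF receptor gene Kdr at 2.84 ± 3.03 against 0.219 ± 0.354 CPM (camera adjusted p = 0.0406; adjusted p = 0.368 with an estimated correlation). Oocyte markers and the oocyte growth and zona list rose (camera adjusted p = 0.0444 for both; adjusted p = 0.618 and 0.620 with an estimated correlation). Each of these 6 calls ended without single libraries. They were dextran replicate 1 (0.0757) or 4 (0.0631) for oxidative phosphorylation, and control replicate 3 (0.0963) or 4 (0.0548) or dextran replicate 1 (0.0681), 2 (0.113) or 3 (0.0682) for endothelial markers. The p53 list lost its call without control replicate 1 (0.0641) or 2 (0.267) or dextran replicate 1 (0.0718) or 3 (0.0571). The hypoxia list lost it without control replicate 1 (0.112) or 2 (0.267) or dextran replicate 1 (0.0718), 3 (0.0834) or 4 (0.0764). The 2 oocyte lists lost theirs without blebbistatin replicate 1 (0.0635 for both), control replicate 1 (0.112 for the markers, 0.134 for growth) or 2 (0.805 and 0.539) or dextran replicate 1 (0.0681 and 0.0740) or 2 (0.1995 and 0.377). The markers also lost it without dextran replicate 3 (0.0571). Gdf9, Bmp15 and Zp3 stood at 6180 ± 835, 1671 ± 351 and 2348 ± 629 CPM against 6142 ± 1540, 1509 ± 348 and 2330 ± 196.

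By edgeR 0 of 16749 genes passed for dextran in oocytes, with 890 at an unadjusted p under 0.05 (301 higher, 589 lower), 0 by limma voom and 3 by DESeq2. The genes of smallest p were Slamf7 (log2 change 1.67 ± 0.44), Csmd3 (0.73 ± 0.20) and Zscan5b (1.08 ± 0.31) on the higher side. On the lower side they were the fatty acid oxidation enzyme Hadh (−2.15 ± 0.46), the mRNA export adaptor Fyttd1 (−1.21 ± 0.28) and Itm2c (−1.10 ± 0.27). All 6 had an edgeR adjusted p = 0.857 and did not pass. Hadh was at 187 CPM in control granulosa cells, scaled over all 24 libraries. In oocytes it was at 23.3 CPM in control replicate 2 against 5.06 to 6.66 in the other controls. Granulosa cell RNA carried into that library may account for part of its fall, which was not tested. The libraries did not overlap for 400 genes, 2.39% against 2.86% by chance. Of 34 lists 10 passed (3 rising, 7 falling), 0 with an estimated correlation and 0 by fry, where 3 and 5 lists had an unadjusted p under 0.05. The real grouping gave a smaller camera p than every other split for 1 of the 10. Camera called 5 without control replicate 2, 4 without dextran replicate 1, and 4 without control replicates 1 and 2, a setting chosen after seeing the data. In that last setting ribosomal protein genes kept an adjusted p of 5.02e-14 and cholesterol synthesis genes had 0.0561.

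Between oocytes of the 2 treatments camera called 1 list, for which another split of the libraries gave a camera p as small. Ribosomal protein genes were higher with blebbistatin than with dextran (72 of 77 positive, median 0.12, camera adjusted p = 9.90e-08; adjusted p = 0.888 with an estimated correlation). None of them passed adjusted over the list alone by edgeR, and fry called 0 lists. Rplp1, a protein of the ribosomal stalk, was at 87.3 ± 16.5 against 59.9 ± 6.36 CPM. The mitochondrial calcium uniporter regulator Smdt1 was at 20.7 ± 5.47 against 10.8 ± 1.14, and Gripap1 at 13.3 ± 2.99 against 5.71 ± 2.56. Tut7, which adds uridines to RNA ends, was at 25.5 ± 5.73 against 42.4 ± 4.23 CPM, with log2 changes of −0.75 ± 0.18 for Noct and −0.49 ± 0.12 for Anp32b. None of these 6 passed (edgeR adjusted p = 0.999 each). By edgeR, limma voom and DESeq2 0 genes passed. By edgeR 682 had an unadjusted p under 0.05, and 464 did not overlap, 2.77% against 2.86% by chance. The number of lists was 4 without blebbistatin replicate 1, control replicate 3 or dextran replicate 2, and 2 without blebbistatin replicate 4 or dextran replicate 1 or 3.

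The cell types were then compared in a joint fit that gave each gene the same spread in both. Fitted apart, the common dispersion was 0.302 in granulosa cells and 0.129 in oocytes. A change within granulosa cells may therefore be judged against too small a spread. A test of the difference between the cell types, the oocyte change minus the granulosa cell change, called 10 of 20601 genes for blebbistatin (9 positive, 1 negative), with CPM here scaled over all 24 libraries. Tpm1 was the negative one. It stood at 559 against 160 CPM in granulosa cells and 28.8 against 32.6 CPM in oocytes, a difference of −1.98 ± 0.36 (edgeR adjusted p = 0.0460; 0.00604 to 0.326 over 27 alternatives, of which 6 kept the call). Uchl1 stood at 22.2 against 49.3 CPM in granulosa cells and at 1285 against 1090 CPM in oocytes, a difference of 1.39 ± 0.22 (edgeR adjusted p = 0.0261; 0.000782 to 0.195 over 27 alternatives, of which 19 kept the call). For the serine protease gene Htra4 (ENSMUSG00000037406) the levels were 56.3 against 59.7 CPM in oocytes and 0.0132 against 0.904 CPM in granulosa cells, and the difference of 5.45 ± 0.75 passed in all 27 alternatives (edgeR adjusted p = 0.00670; 0.000675 to 0.0218). Its size ran from 4.54 to 6.99 and, with a granulosa level near 0, depends on the prior count. The tight junction gene Ocln was at 21.5 against 22.1 CPM in oocytes and at 0 against 1.24 CPM in granulosa cells, so its fitted difference depends on the prior count too (edgeR adjusted p = 0.0304; 0.00806 to 0.0718 over 27 alternatives, of which 16 kept the call). The other 6, named after their values were seen, were 1700016H13Rik, Fbxl21, Kcnh1, 9130204K15Rik, Mapk11 and Jag2. The microtubule gene Tuba4a and the zinc finger gene Bnc2 had differences of −0.94 ± 0.18 and −1.83 ± 0.35 and did not pass (edgeR adjusted p = 0.0666 and 0.0617), nor did Ftl1 (−1.61 ± 0.62, 0.348).

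Single libraries also ended the calls of 3 of these genes. Tpm1 lost its call without granulosa blebbistatin replicate 1 (0.0712) or 3 (0.0593), granulosa control replicate 2 (0.0614) or 3 (0.146) or granulosa dextran replicate 2 (0.0699) or 4 (0.0655). It also lost it without each oocyte library, with 0.0793, 0.0561, 0.120 and 0.123 for blebbistatin replicates 1 to 4, 0.102, 0.123, 0.0817 and 0.0603 for control replicates 1 to 4, and 0.0720, 0.0623, 0.0643 and 0.0619 for dextran replicates 1 to 4. Uchl1 lost its call without granulosa control replicate 3 (0.0608), oocyte blebbistatin replicate 1 (0.0680), 2 (0.0524) or 3 (0.0617), oocyte control replicate 1 (0.0649) or 2 (0.0529) or oocyte dextran replicate 4 (0.0537). Ocln lost it without granulosa blebbistatin replicate 1 (0.0717), granulosa control replicate 3 (0.0528) or oocyte blebbistatin replicates 1 to 4 (0.0680, 0.0561, 0.0619 and 0.0682). It also did without oocyte control replicate 1 (0.0649) or 3 (0.0718) or oocyte dextran replicate 1 (0.0502), 3 (0.0524) or 4 (0.0537).

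The number of genes called for blebbistatin was 2 without oocyte blebbistatin replicate 1, 2 or 3, oocyte control replicate 1 or oocyte dextran replicate 4. It was 3 without granulosa control replicate 3, oocyte blebbistatin replicate 4 or oocyte dextran replicate 1, 4 without oocyte control replicate 3 or oocyte dextran replicate 3, and 6 without oocyte control replicate 2 or oocyte dextran replicate 2. It was 18 without granulosa dextran replicate 1 or 4, 22 without granulosa blebbistatin replicate 4, 26 without granulosa dextran replicate 3 and 103 without granulosa blebbistatin replicate 2. For dextran 0 of 20601 genes passed by edgeR and 0 by limma voom, with 1912 at an unadjusted p under 0.05. The smallest adjusted p was 0.246, reached by Id1 (difference −2.63 ± 0.49), the actin cross-linker Flna (−2.70 ± 0.54), Fyttd1 (−1.50 ± 0.30), Dtx3 and Svopl. On the positive side Zmat4, Arhgap15 and Tex19.1 had 0.266, all 3 at 0 CPM in dextran granulosa cells. That count was 91 without oocyte control replicate 4, 6 without granulosa control replicate 4, 4 without granulosa dextran replicate 1, 2 without oocyte dextran replicate 3 and 1 without granulosa control replicate 2 or granulosa dextran replicate 4.

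Both treatments were compared with the same controls, which makes their changes correlate without any effect. Across the 15370 genes of granulosa cells the blebbistatin and dextran log2 changes correlated with r = 0.35. In 20 simulations of unchanged groups that shared simulated controls the mean was 0.49. The simulations drew all libraries, controls included, around the mean of all libraries with genes independent of each other. They therefore lack the make-up of the real controls, such as the granulosa cell transcripts of single control oocyte libraries, and a value above them is not read as a shared effect. The covariance was 0.190 against 0.283 simulated, a difference of −0.0934. At an unadjusted p under 0.05, 145 genes were higher with both treatments (19.6 for independent lists, 89.1 simulated) and 64 lower with both (8.00 and 44.6). With the controls split, 2 for each treatment, r ran from 0.0786 to 0.208 and was above 0 in 6 of 6 assignments. In oocytes r was 0.65 against 0.50 simulated, and the covariance 0.241 against 0.147, a difference of 0.0942. There were 54 genes higher with both (4.13 independent, 94.3 simulated) and 129 lower with both (16.0 and 54.4). With split controls r ran from −0.228 to 0.274 and was above 0 in 4 of 6 assignments. Genes are not independent replicates, so these values carry no p.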

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

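The tests of regrouped samples, of macrophages and of the spread among granulosa cell markers were chosen after the results were seen, while the tests with the stromal marker level and with the subtracted granulosa cell share were written before theirs. In this section the value after ± beside a list's median is an SE over the list's members. Those are not independent replicates, so it does not measure the spread between libraries.

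In blebbistatin granulosa libraries actin, matrix and stromal genes rose together. Macrophages in replicates 1 and 2 are not the whole cause, since the actin list kept a camera adjusted p of 9.98e-08 without those libraries. More stromal or smooth muscle cells in the pools may account for part of it, so each library's stromal marker level was put in the edgeR fit. The median log2 change of the 28 actin genes outside the stromal list went from 0.47 ± 0.24 to 0.23 ± 0.26 (20 positive, limma camera adjusted p = 4.42e-05). That of the 23 AhR and NRF2 genes went from 0.36 ± 0.25 to 0.22 ± 0.27 (14 positive, 0.000116). Both lists stayed above other genes while their medians came within their SE of 0. A stromal share and an effect of blebbistatin on granulosa cells cannot be told apart for these lists. Both medians were under 2 SE from 0 before the correction. The marker level also parted the groups, at 3.70 to 4.99 with blebbistatin and 1.19 to 3.41 in controls. With that level in the fit, single genes moved less. Ftl1 kept a log2 change of 1.03, Tpm1 went from 1.80 to 1.40 and Hmox1 from 1.26 to 1.22.

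Granulosa cell and FSH response genes fell in the blebbistatin granulosa libraries. A lower share of granulosa cell RNA in the pools would lower all such genes alike, and 6 of 18 granulosa cell markers of at least 5 CPM had a log2 change more than 2 SE from the list's median. As 3 of 35 splits of the libraries gave as many (highest other 6), a lower share and an effect of blebbistatin on FSH response within granulosa cells cannot be told apart. With the stromal marker level in the fit, Inha had a log2 change of −0.47 and Inhbb of −2.93.

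In oocyte libraries granulosa cell, cholesterol and ribosomal protein genes were lower than in controls. Granulosa cell RNA carried into control oocyte libraries may account for most of the falling lists, as 2 of 10 for blebbistatin (cholesterol, adjusted p = 0.000127 by limma camera, and mitochondrial, 3.88e-05) and 2 of 7 for dextran (cholesterol, 2.60e-06, and ribosomal protein, 9.44e-06) kept their call once each library's estimated granulosa cell share was subtracted. That share was the median over 10 granulosa cell markers, several of them also in the FSH list. The lost calls of the marker and FSH lists were therefore built in. In control replicate 2 the single genes gave 2.91% to 24.3%, around the 8.80% used. For blebbistatin the subtraction moved the median log2 change from −0.28 to −0.24 ± 0.14 for cholesterol genes and from −1.10 to −1.59 ± 0.31 for mitochondrial genes. It cannot decide on carry-over for these lists, as it assumes the profile of each treatment's own granulosa pools. Those pools held 5.77% mitochondrial counts with blebbistatin against 3.05% in controls. In the oocyte libraries that share was 0.225% and 0.443% in control replicates 1 and 2 and 0.0426% and 0.0871% in 3 and 4. With blebbistatin it was 0.0640% to 0.124%. Without control replicates 1 and 2 neither list was called (0.471 and 0.213 by limma camera). For dextran the subtraction moved the median from −0.48 to −0.14 ± 0.19 for cholesterol genes and from −0.25 to −0.11 ± 0.04 for ribosomal protein genes. Without control replicates 1 and 2 these lists had an adjusted p of 0.0561 and 5.02e-14 by limma camera. For the cholesterol list carry-over and an effect of dextran on oocytes cannot be told apart, because the median shrank while the call stayed. Control replicates 3 and 4 held 0.214% and 0.0683% of the granulosa pools' level, and the dextran libraries at most 0.327%. For the ribosomal protein list this argues against carry-over as the whole cause. Its median shrank too, and it did not pass with an estimated correlation, so an effect of dextran is not shown.

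Regrouping the libraries asked whether chance can be excluded. Every split reaches a count of 0, so where edgeR called 0 genes that count says nothing about chance, and genes at an unadjusted p under 0.05 were counted too. A share of 1 of 35 splits is the smallest these designs give, and it is not adjusted for the number of such tests. For blebbistatin in granulosa cells only the real split reached the 1 gene called by edgeR (highest other 0) or the 28 called by limma voom (highest other 1), 1 of 35 for each. That share is not adjusted over the many such tests, which were chosen after the results were seen, so chance is not excluded for the limma voom count. For the edgeR count the margin is a single gene, which the replicate block or only the 2 groups compared bring to 0, so it is not taken to exclude chance. Chance cannot be excluded for the 415 called by DESeq2 (2 of 35 splits, highest other 447), the 1602 at unadjusted p under 0.05 (2 of 35, highest other 1878) or the 16 lists (5 of 35, highest other 18). For dextran in granulosa cells edgeR called 0 genes (reached by 35 of 35, highest other 42). Chance cannot be excluded there for the 523 at unadjusted p under 0.05 (4 of 35, highest other 1252), the 143 by limma voom (2 of 35, highest other 728), the 45 by DESeq2 (3 of 35, highest other 313) or the 16 lists (10 of 35, highest other 19). A split that set dextran replicate 1 with control replicates 1 to 3 against the rest gave the 42, 728 and 313, against real counts of 0, 143 and 45. That split also divides the libraries by granulosa marker level. It was 8.54, 8.09 and 8.50 in control replicates 1 to 3 and 8.30 in dextran replicate 1. In control replicate 4 it was 7.79, and in dextran replicates 2 to 4 it was 7.89, 7.63 and 7.78. Whether this difference is why the split gave more was not tested. For blebbistatin against dextran in granulosa cells edgeR called 0 genes, limma voom 0 and DESeq2 310 (0 reached by 35 of 35, highest other 0). The 1358 at unadjusted p under 0.05 were reached by the real split alone (1 of 35, highest other 1112). That share is again unadjusted over the tests, so chance is not excluded for this count. Nor can it be excluded for the 12 lists (6 of 35, highest other 15).

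In oocytes edgeR called 0 genes in each comparison (reached by 35 of 35, highest other 1 in each), limma voom 2, 0 and 0, and DESeq2 19, 3 and 0 for blebbistatin, dextran and their difference. Chance cannot be excluded for the genes at unadjusted p under 0.05, which were 686 (14 of 35, highest other 1741), 890 (13 of 35, highest other 2375) and 682 (14 of 35, highest other 1353). Nor can it for the 12 lists with blebbistatin (5 of 35, highest other 16), the 10 with dextran (5 of 35, highest other 15) or the 1 between the treatments (28 of 35, highest other 8). For the difference between cell types with blebbistatin it cannot be excluded for the 10 genes by edgeR, reached by 3 of 40 regroupings (highest other 32, for a reason not tested). Nor can chance be excluded there for the 2322 at unadjusted p under 0.05 (10 of 40, highest other 2842). With dextran edgeR and limma voom called 0 genes (reached by 40 of 40, highest other 15), and chance cannot be excluded for the 1912 at unadjusted p under 0.05 (10 of 40, highest other 2608).

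By the edgeR interaction test 10 genes passed for a difference between cell types in the blebbistatin effect, a count for which chance cannot be excluded. Among them the oocyte change minus the granulosa cell change was 5.45 for Htra4, 1.39 for Uchl1, 7.44 for Ocln, which was at 0 CPM in blebbistatin granulosa cells so that its value depends on the prior count, and −1.98 for Tpm1.

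Single libraries stood far from the other 3 of their group in 19 of 231 groups tested (2 of 72 library measures, 17 of 159 genes), where chance gives about 11.6. The gap to the nearest library, as a share of the group's range, is given for each. The immune cell marker level of granulosa control replicate 4 was 0.658 against 0.259 to 0.322 (0.842). The ribosomal protein share of oocyte dextran replicate 2 was 1.10% against 0.906% to 0.910% (0.978). Ankrd1 was at 8.13 CPM in granulosa blebbistatin replicate 1 against 0 to 0.0536 (0.993) and at 0.548 in granulosa dextran replicate 1 against 0 (1). Cyp19a1 was at 3.00 CPM in granulosa blebbistatin replicate 4 against 0 to 0.322 (0.893) and at 6.90 in granulosa dextran replicate 1 against 0 to 0.545 (0.921). In that dextran library Amh was at 379.7 CPM against 43.0 to 58.2 (0.955) and Slc5a3 at 43.7 against 25.1 to 28.0 (0.843). Myo6 was at 90.8 CPM in granulosa blebbistatin replicate 1 against 104 to 107 (0.851) and Prkag2 at 71.8 in granulosa control replicate 1 against 88.0 to 90.7 (0.856). In granulosa control replicate 4 Ccn2 was at 3.60 CPM against 0.181 to 0.654 (0.862), Septin4 at 34.6 against 47.1 to 49.5 (0.841) and Dhh at 69.7 against 134 to 137 (0.951). Col4a4 was at 13.3 CPM in granulosa dextran replicate 4 against 5.46 to 6.52 (0.865) and Septin4 at 10.5 in granulosa dextran replicate 3 against 20.6 to 21.4 (0.922). In oocytes Ash2l was at 42.6 CPM in blebbistatin replicate 3 against 36.8 to 37.1 (0.944) and Anp32b at 293 in control replicate 2 against 222 to 229 (0.895). Hadh was at 23.3 CPM in oocyte control replicate 2 against 5.06 to 6.66 (0.913) and at 2.43 in oocyte dextran replicate 3 against 2.29 to 2.31 (0.837).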

How the results depend on the processing

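Settings that left out more than 1 library or combined 2 choices were chosen after seeing the data. Of 6831 values of named genes under the alternatives, 6623 kept their side of the threshold and direction, 160 passed where the original did not, 48 no longer passed and 0 called changes reversed, while 118 uncalled values changed sign. With RLE size factors 0 of 67 list calls were lost or flipped, and the median of all genes moved by at most 0.0287. Where counts moved with fewer libraries or another tool, the cause was not tested. At this depth and spread 40% of simulated 2-fold and 69% of 4-fold changes were found in granulosa cells. These were changes of genes of at least 5 CPM, simulated independently of each other, and depth was not varied.

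For blebbistatin in granulosa cells the number of genes, 1 by edgeR, was 23 with no count filter, 28 with limma voom, 415 with DESeq2, 0 with only the 2 groups compared (1067 at unadjusted p under 0.05), 10 with limma voom without blebbistatin replicate 1 and 26 without blebbistatin replicates 1 and 2. For dextran in granulosa cells, 0 genes by edgeR, it was 4 with no count filter, 143 with limma voom, 45 with DESeq2 and 1 with only the 2 groups compared. For blebbistatin against dextran in granulosa cells, 0 genes by edgeR, it was 1 with no count filter and 310 with DESeq2. For blebbistatin in oocytes, 0 genes by edgeR, it was 4 with no count filter, 2 with the stricter filter, 2 with limma voom and 19 with DESeq2. For dextran in oocytes, 0 genes by edgeR, it was 3 with DESeq2. For the difference between cell types with blebbistatin, 10 genes, it was 17 with limma voom.

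With an estimated correlation and with fry the number of lists went from 16 to 0 and 7 for blebbistatin in granulosa cells, from 16 to 2 and 1 for dextran in granulosa cells, and from 12 to 0 and 2 between these treatments. Of these fry calls 5, 1 and 0 were among the lists called by camera. For blebbistatin camera called 13 rising and 3 falling and fry 3 rising and 4 falling, and between the treatments camera called 8 higher and 4 lower and fry 0 higher and 2 lower. In oocytes it went from 12, 10 and 1 to 0 and 0 for blebbistatin, dextran and their difference. Without oocyte control replicates 1 and 2 it was 0 for blebbistatin and 4 for dextran.

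Leaving out each library in turn gave 0 to 115 genes for blebbistatin in granulosa cells, 0 to 4 for dextran and 0 to 3 between the treatments, and 7 to 17 lists between the treatments in granulosa cells. In oocytes it gave 0 to 15 lists for blebbistatin, 4 to 13 for dextran and 1 to 4 between the treatments. For the difference between cell types it gave 2 to 103 genes with blebbistatin and 0 to 91 with dextran.

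The replicate number as a block gave 0 genes by edgeR for blebbistatin in granulosa cells (1571 at unadjusted p under 0.05), 0 for dextran and between the treatments in granulosa cells (619 and 1395), 0 for the 3 oocyte comparisons (640, 698 and 653), and 5 for the difference between cell types with blebbistatin. The number of lists under the block was 14, 16 and 12 in granulosa cells. Same-numbered libraries showed no clear tendency to deviate together. Their correlations ran from −0.202 to 0.247 in granulosa cells, with 2 of 12 pairs over 0.1. Closest to their own number were 5 of 12 libraries in granulosa cells and 3 of 12 in oocytes. The mean correlation was 0.0337 for same-numbered against −0.0105 for other pairs in granulosa cells, and 0.0224 against −0.00751 in oocytes. These small differences neither show nor exclude that the numbers pair the samples.

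The correlation of the blebbistatin and dextran changes, 0.35 in granulosa cells, was 0.0850, 0.0792 and 0.0786 with control replicates 3 and 4, 2 and 4 or 2 and 3 given to blebbistatin and the others to dextran, and 0.167, 0.141 and 0.208 with 1 and 2, 1 and 3 or 1 and 4. In oocytes, 0.65, it was reversed at −0.0280 and −0.228 with replicates 1 and 2 or 3 and 4 given to blebbistatin, and it was 0.178, 0.246, 0.148 and 0.274 with 1 and 3, 2 and 4, 1 and 4 or 2 and 3. Splitting removes the covariance of shared controls by construction.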

Other observations

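Lists that no comparison called still held single members that moved, all values here being read after the results were seen. Among 19 cell junction and transzonal projection genes in granulosa cells, 3 were lower with blebbistatin than in controls adjusted over the list alone, although the list was not called (limma camera adjusted p = 0.677). The junctional adhesion molecule Jam2 was at 293 ± 38.5 against 419 ± 55.8 CPM and N-cadherin (Cdh2) at 48.0 ± 16.0 against 98.3 ± 23.9. The tight junction gene Ocln was near the floor, at 0 against 1.37 ± 0.865 CPM, in libraries that detected fewer genes (18410 ± 2791 against 22656 ± 1478). Against dextran 4 members were lower adjusted over the list alone (limma camera adjusted p = 0.265), these 3 and Gja1, which couples granulosa cells to each other, at 6713 ± 881 against 8682 ± 458 CPM.

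Of 15 osmotic stress genes 1 was higher and 1 lower with blebbistatin than with dextran in granulosa cells adjusted over the list alone (limma camera adjusted p = 0.561). These were the aldo-keto reductase Akr1b8, at 41.5 ± 11.6 against 12.9 ± 8.35 CPM, and the taurine transporter Slc6a6, at 348 ± 29.96 against 441 ± 48.9. Cited4, a member of the ovulatory list, was higher with dextran than in controls adjusted over the list alone, at 10.3 ± 5.12 against 2.60 ± 1.38 CPM, with the list not called (limma camera adjusted p = 0.516). Cell cycle, oocyte meiotic maturation, oocyte RNA storage, theca cell and ovarian surface epithelium lists had smallest limma camera adjusted p-values of 0.594, 0.145, 0.102, 0.0977 and 0.606 over the comparisons in which they were tested.

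Ftl1 has near-identical copies in the genome. Relative to the unscaled library total, the copy Ftl1-ps1 was at 7.22 CPM in blebbistatin granulosa cells, 2.88 in controls and 4.34 with dextran, far below Ftl1 itself. How salmon divided reads among them is not given in the sources used here.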
